A study of Oryza sativa with 6 samples.

How the data were processed

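Total RNA from inflorescences 2 mm long was measured on 6 Affymetrix arrays, 3 from the osmads32 mutant and 3 from wild-type rice. Per the labels' protocols, plants grew in a paddy field, RNA was extracted with Trizol, and biotinylated cRNA was made from 500 ng of total RNA with an Affymetrix 3′ labelling kit. The authors deposited log2 expression values, 1 per probe set and array, for 57381 probe sets. The submitters' processing notes name RMA, which corrects background, quantile-normalizes the arrays and summarises the probes of a set, and the Partek software. Their versions, and any filter, are not given in the sources used here. That the deposited values are on a log2 scale was inferred from the values, which lie between 1.81 and 13.66 with nearly equal quartiles on all arrays. Quantile normalization gives all arrays about the same distribution of values, so a shift of the whole transcriptome in one direction cannot be seen, and RMA compresses differences near the background. Scanner intensities were not used here, and no detection call was made, so a low value is a level near the background, not an absence.

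Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate plants or plots, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision of every value. The replicate numbers were not used to pair samples.

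Gene names came from the platform annotation of the probe sets, updated through a RefSeq gene table (assembly ASM3414082v1) that was used for names only. Of the 57381 probe sets, 22531 were in the annotation, 22436 of them with 1 gene and 95 with several. The probe sets with 1 gene covered 17905 genes, and the identifiers of all 17905 were in the RefSeq table. A name other than a locus symbol or a clone name was found for 2452 of these genes. Probe sets with several genes were named for none, and 34727 of the tested probe sets had no gene in the annotation. For tests on genes, each gene was represented by its probe set with the highest mean over the 6 arrays. Several probe sets were present for 3444 genes, and in 11 of these genes probe sets passed the test in both directions.

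The 123 AFFX control probe sets were left out, and the remaining 57258 were compared between osmads32 and wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), on the log2 values as deposited. P-values were adjusted by the Benjamini-Hochberg method over all probe sets, and separately over the 17905 genes in the fit on genes. The threshold was an adjusted p below 0.05, and probe sets that also differed by at least 1 on the log2 scale, a fold of 2, were counted separately. Differences are given as osmads32 minus wild type on the log2 scale. With 3 arrays against 3, the smallest two-sided p of an exact permutation test on a single gene is 0.1, so no such test could pass 0.05.

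The 24 lists of at least 5 measured genes were fixed before the data were examined. They cover floral organ identity genes, other MADS-box genes, SBP (SPL), TCP, YABBY and homeodomain-leucine zipper transcription factors, inflorescence and spikelet meristem genes, meristem genes (KNOX, CLV and WUS types), meiosis, tapetum and anther, auxin, cytokinin, gibberellin, jasmonate with wounding and pathogenesis-related proteins, cell cycle, core histones, cytosolic ribosomal proteins, cell-wall expansion, class III peroxidases and laccases, wax and lipid transfer, diterpenoid phytoalexins, photosynthesis in green tissue, heat shock, and the circadian clock. Of the names on the lists fixed by gene name, 25 matched no gene in the tables used here. Each list was tested with limma's camera, with the preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. List p-values were adjusted over the 24 lists. Members' own calls were counted over all genes and adjusted over the list alone.

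The rule for named genes was also fixed before the data were examined. It took OsMADS32, every measured floral organ identity gene, the 10 named genes with the largest increase and the 10 with the largest decrease among those past the threshold with all arrays of one group on one side of the other group, and for every other list the 4 members with the smallest p. Genes named outside this rule are said to be chosen after their values were seen.

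The fits were tested on simulated data in which 200 features were changed. Of 67 probe sets changed by 0.5 on the log2 scale, 65.7% were recovered, and 100% of those changed by 1 or by 2 were, with 14 false calls among 57058 unchanged probe sets. In the fit on genes, 85.1% of 67 genes changed by 0.5 and 100% of those changed by 1 or by 2 were recovered, with 6 false calls. A planted shift of 1 in every gene of a single list was found, and none of the other lists passed. The simulated noise was independent between genes, and far fewer features were changed than the data called. The simulation therefore cannot show how camera's preset behaves where the genes of a list vary together, or give the error rate in the data.

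Alternatives covered a replicate block, repeated quantile normalization, centring on the array median, leaving out dim probe sets, an intensity trend with robust variance, array weights, leaving out each array, limma's treat with a minimum fold of 1.2, an adjusted p below 0.01, the mean of a gene's probe sets, and the other list tests named here. Leaving out the 64 reporter control probe sets was added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.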

Results

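Gene expression was profiled in young inflorescences of the rice osmads32 mutant and of the wild-type cultivar Zhonghua 11, with 3 arrays per genotype. OsMADS32 is a member of the MADS-box family of transcription factors, many of which specify floral organs. The inflorescences were 2 mm long, a length that the submitters give as the onset of inner floral organ development, and the comparison asks which genes lie downstream of OsMADS32. The 6 arrays had median log2 values of 4.11 to 4.15, lower quartiles of 3.02 to 3.08 and upper quartiles of 6.62 to 6.70. Across 57258 probe sets, arrays of the same genotype correlated at 0.995 to 0.998 and arrays of different genotypes at 0.989 to 0.991 (Pearson's r across probe sets, which are not independent replicates). The standard deviation of the differences between a pair of arrays was 0.163 to 0.226 within a genotype and 0.318 to 0.352 between genotypes. The tables used here paired no gene with the name OsMADS32, and the level of the mutated gene, which would check the sample labels, was not analysed here.

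Individual floral regulators, heat-shock genes and circadian clock genes differed between osmads32 and wild type, in both directions. OsMADS6 and OsMADS17, both of the AGL6 class of floral MADS-box genes, rose by 1.05 and 0.98 on the log2 scale, while the AP1/FUL-class genes OsMADS14 and OsMADS18 fell by 0.59 and 0.35. Of the 45 measured heat-shock genes, 21 rose, led by the heat-shock transcription factor HSFA2A at +4.47. The clock gene LHY, a morning-expressed repressor, rose by 2.85, while LUX, PRR1 and GI, which peak later in the day, fell by 3.15, 1.52 and 1.51.

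Of 57258 probe sets, 5133 (8.96%) changed in osmads32, 1973 of them higher and 3160 lower. The median size of these changes was 0.47 on the log2 scale. At least 2-fold changes were found for 584 probe sets, of which 385 were higher and 199 lower, so that larger changes leaned toward increases. Among 17905 genes, 1813 rose and 3427 fell, 5240 (29.3%) in all, with a median size of 0.35, and 353 of them changed at least 2-fold (224 higher, 129 lower). The median difference over all genes was -0.040. Repeated quantile normalization brought it to -0.030, with 1990 genes higher and 3160 lower. Centring on the array median moved it to -0.048, with 1622 higher and 3272 lower. Neither removed this small offset, so how far it adds to the count of decreases was not settled. All 5133 probe sets had the 3 arrays of one genotype above the 3 of the other, which passing the test nearly requires, so it is no separate support. Such a separation was found in 27.6% of all probe sets, against 10% by chance. The count of probe sets depended on single arrays, falling to 2579 without osmads32 replicate 3, 2787 without wild-type replicate 1, 3010 without wild-type replicate 2 and 3215 without wild-type replicate 3, and to 1145 (582 higher, 563 lower) when a change beyond 1.2-fold was required. The count of genes fell to 3141 without osmads32 replicate 3 and came to 8340 with array weights, whereas the 2-fold count stayed between 549 and 611 under every alternative run.

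Floral organ identity genes went both ways. Of 18 measured genes, 4 rose, 4 fell and 10 did not pass the test (4 and 5 when adjusted over the list alone). OsMADS6, which acts in floral organ and meristem identity, stood at 10.58 ± 0.044 in osmads32 and 9.53 ± 0.035 in wild type (SD, n = 3; SE of the difference 0.050, adjusted p = 5.6e-05). Its relative OsMADS17 was at 9.01 ± 0.054 against 8.03 ± 0.13 (adjusted p = 0.000311). DROOPING LEAF (DL), the YABBY gene that specifies the carpel, rose by 0.74 to 7.16 ± 0.078 (adjusted p = 0.00175). The SEPALLATA-class gene OsMADS1 rose by 0.46 (adjusted p = 0.0199), a call that ended without osmads32 replicate 1 or replicate 3 (highest adjusted p = 0.0627).

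The floral genes that fell are known to act in the step to spikelet and floral meristems, but a shift of genes with this role was not tested. OsMADS14 fell by 0.59 to 10.81 ± 0.12 (SD, n = 3; adjusted p = 0.00221), and 3 of its 4 probe sets passed in this direction. OsMADS18 fell by 0.35 to 10.65 ± 0.0094 (adjusted p = 0.00246). OsMADS34 fell by 0.44 (adjusted p = 0.0252) and OsMADS15 by 0.21 (adjusted p = 0.0260). Both of these calls were fragile: that of OsMADS34 ended without osmads32 replicate 3 or any 1 wild-type array, and that of OsMADS15 ended without replicate 1 or 3 of either genotype, in 5 of 13 alternatives in all, and in the fit on all probe sets (adjusted p = 0.111).

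Floral genes that did not pass included the B-class genes, which specify lodicules and stamens. OsMADS2 differed by 0.01, OsMADS4 by 0.09 and OsMADS16 by -0.31 (95% confidence interval -0.76 to 0.14). The C-class genes OsMADS3 and OsMADS58, which act in stamens and carpels, differed by -0.14 and 0.22. OsMADS3 was at a low level, 3.54 in osmads32 and 3.68 in wild type, where a difference could be compressed. OsMADS58 varied between arrays of one genotype with an SD of 0.60 in osmads32. The SEPALLATA-class genes OsMADS5, OsMADS7 and OsMADS8 differed by -0.07, -0.29 and -0.46 (adjusted p = 0.0685 for OsMADS8). Within osmads32, OsMADS58, OsMADS7, OsMADS8 and OsMADS16 were all highest in replicate 1 and lowest in replicate 2. Within wild type they were all lowest in replicate 1. This shared spread between arrays widens their errors, so not passing does not show that these genes were unchanged. The ovule-identity genes OsMADS13 and OsMADS21 were near the background in both genotypes, at 2.91 and 2.37 in osmads32. As a list, floral organ identity genes did not pass camera (adjusted p = 0.59).

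**Figure D1:**
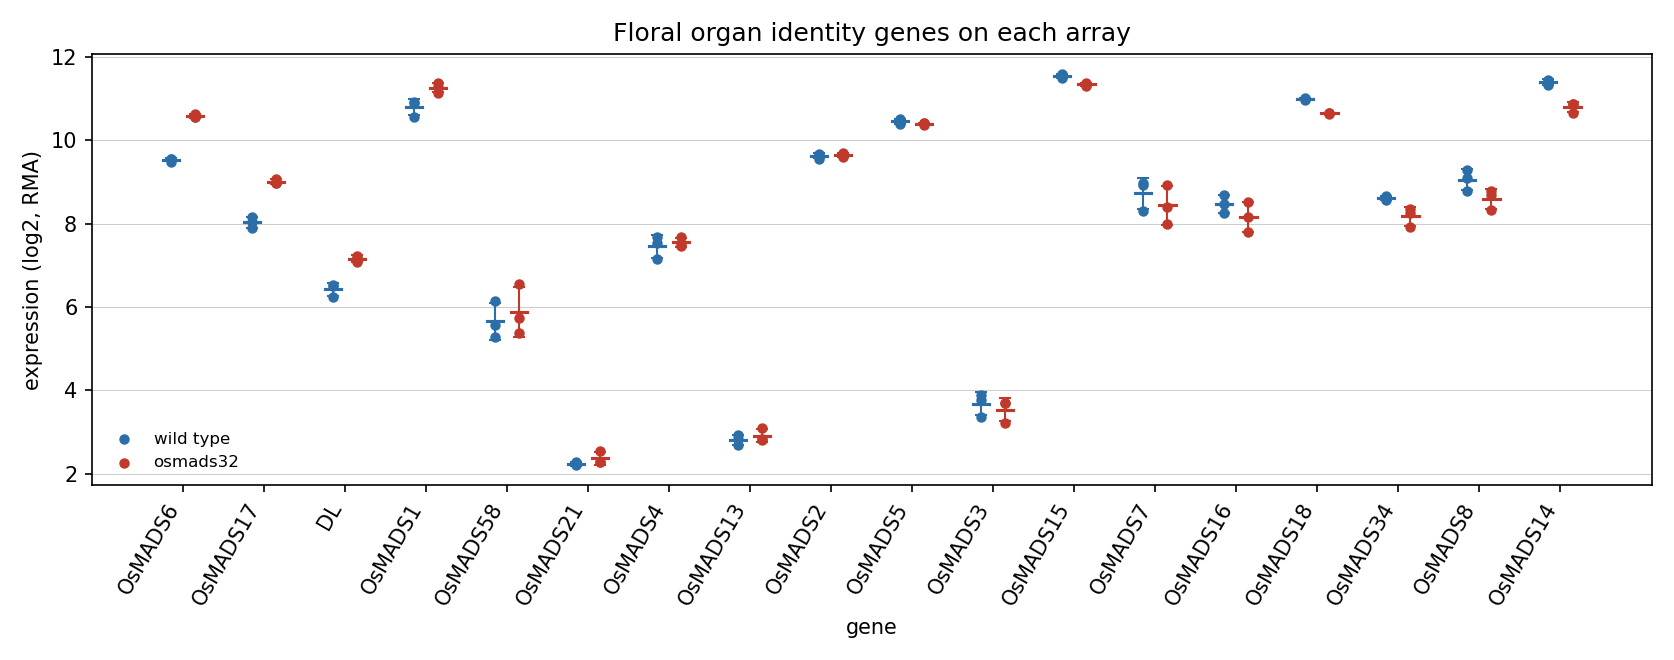
Log2 expression (RMA, vertical axis) of the 18 floral organ identity genes (horizontal axis, ordered by their difference) on each array, with points for the 3 osmads32 arrays in red and the 3 wild-type arrays in blue, horizontal bars at the means and vertical bars for the SD. The osmads32 points of OsMADS6, OsMADS17 and DL lie above all wild-type points, and those of OsMADS14 and OsMADS18 lie below them.

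Among other MADS-box genes, 3 of 14 fell and none rose (0 and 2 when adjusted over the list alone for higher and lower). OsMADS22, an SVP-class gene that acts in meristem identity, fell by 0.90 to 8.19 ± 0.11 (SD, n = 3; adjusted p = 0.00186), OsMADS56 fell by 0.27 and OsMADS50 by 0.18. The OsMADS50 call ended in 11 of 13 alternatives (highest adjusted p = 0.122), and that of OsMADS56 without osmads32 replicate 3 (adjusted p = 0.0523). OsMADS55 differed by -0.94 with an SE of 0.34 and did not pass (adjusted p = 0.0804). The list did not pass camera (adjusted p = 0.65).

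Genes of inflorescence and spikelet meristems moved in 2 of 7 cases, both lower (2 also when adjusted over the list alone). SPL14, which controls panicle branching, fell by 0.56 (adjusted p = 0.00387), and FZP, which fixes spikelet identity, fell by 0.56 (adjusted p = 0.0193), a call that ended without osmads32 replicate 3, wild-type replicate 2 or wild-type replicate 3 (highest adjusted p = 0.0644). In the SBP list, which also holds SPL14, 1 of 11 genes rose and 3 fell (1 and 4 when adjusted over the list alone). SPL12 fell by 0.29, SPL9 by 0.20, and SPL15 rose by 0.21. The SPL9 call ended in 5 of 13 alternatives, among them the fits without osmads32 replicate 3 or any 1 wild-type array (highest adjusted p = 0.0888), and the SPL15 call in 4, among them those without osmads32 replicate 3 or wild-type replicate 2 or 3 (highest adjusted p = 0.0775). Of the 7 YABBY genes, DL and YAB1 rose and YAB5 fell (3 and 1 when adjusted over the list alone). YAB1 rose by 0.88 to 10.42 ± 0.18 in its brightest probe set, while its other probe set was near the background and did not pass (0.05), so that their mean differed by 0.47. The YAB5 change of -0.24 ended in 8 of 13 alternatives (highest adjusted p = 0.123). In the TCP list, PCF2 rose by 0.59 and PCF8 by 0.48, and 5 of 7 genes did not pass (2 and 1 when adjusted over the list alone). The meristem list of KNOX, CLV and WUS types had 0 of 7 genes past limma's test over all genes or adjusted over the list alone, and 2 genes at an unadjusted p under 0.05. None of these lists passed camera (smallest adjusted p = 0.37). Both genotypes were sampled at one inflorescence length, and a difference in stage at that length was not ruled out.

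Many heat-shock genes rose, though a shift of the whole list depended on the test. Of 45 measured members, 21 rose, 2 fell and 22 did not pass (24 and 2 when adjusted over the list alone), with a median difference of 0.19 and a mean of 0.63. HSFA2A, a heat-inducible transcription factor, went from 6.28 ± 0.89 in wild type to 10.76 ± 0.16 in osmads32 (SD, n = 3; adjusted p = 0.000571), and its other 2 probe sets rose by 2.37 and 1.93, so that the mean of the 3 rose by 2.92. The small heat-shock proteins HSP24.1, HSP17.4 and HSP18.1, which bind unfolded proteins, rose by 2.82, 2.50 and 2.33, and HSP18.6 by 1.68. HSP18.0 rose by 2.01 in its brightest probe set, but of its others 1 did not pass (0.16) and 1 fell by 0.32, and the mean over them rose by 0.61. HSFC1B, a heat-shock factor of class C, fell by 2.17 (adjusted p = 0.000236), and HSP17.9B was the other member that fell. The list passed camera with an adjusted p = 1.1e-07, the only one of 24 lists to do so. It did not pass with its estimated inter-gene correlation of 0.142 (adjusted p = 0.715 with an estimated correlation), and the preset test passed for this list, less strongly (smallest adjusted p = 0.00367), in 6 of the 9 other ways of splitting the arrays 3 against 3. Those splits keep part of the genotype difference, so they give no rate of chance passes.

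**Figure D2:**
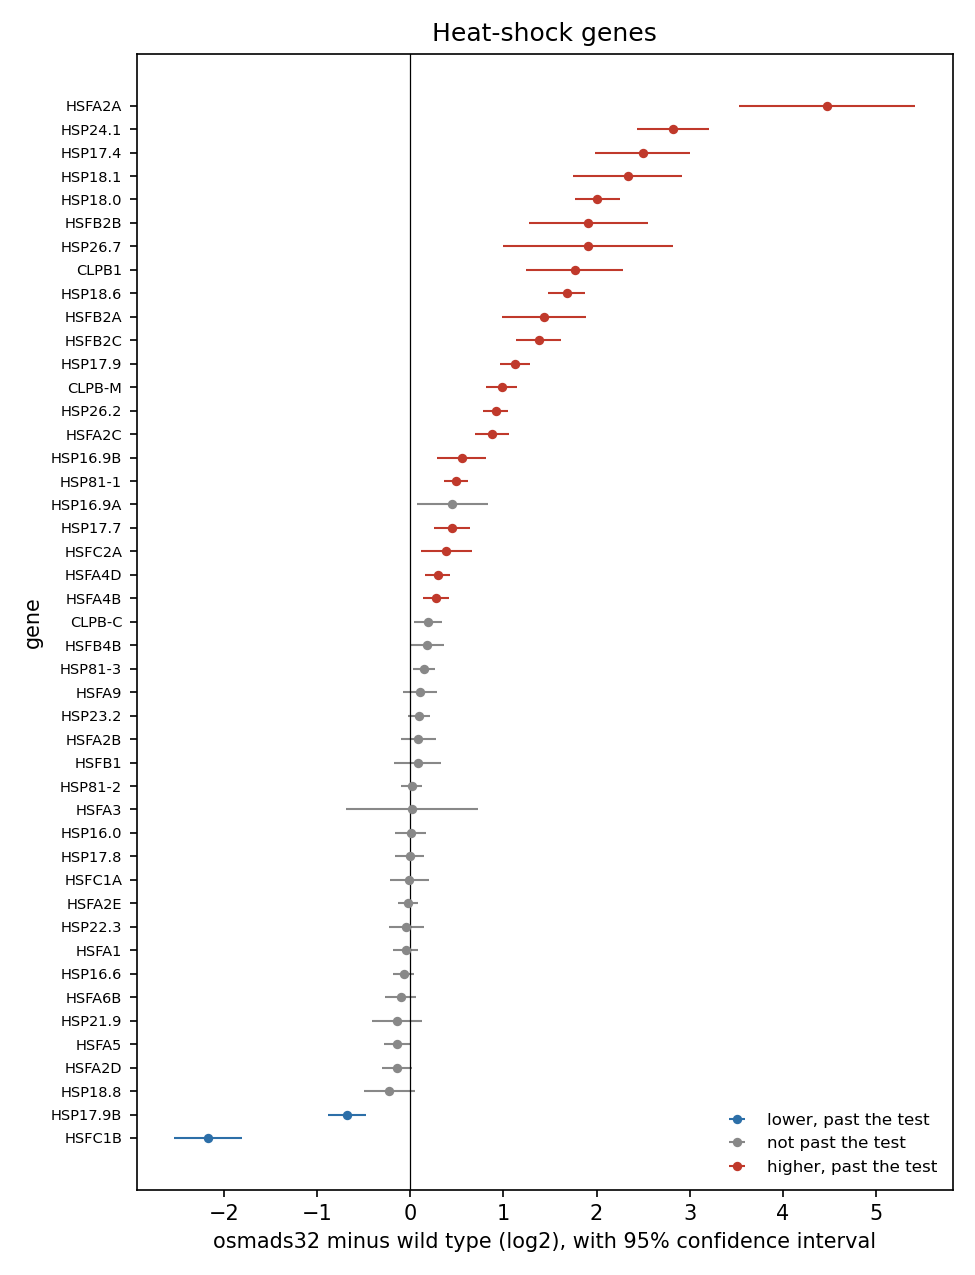
Difference between osmads32 and wild type (log2, horizontal axis) for each of the 45 heat-shock genes (vertical axis), with points for limma's estimates and bars for 95% confidence intervals, in red for the 21 that rose, blue for the 2 that fell and grey for the 22 that did not pass. Increases reach 4.47 for HSFA2A, and the lowest value is -2.17 for HSFC1B.

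Circadian clock genes also differed between the genotypes, with the morning gene LHY higher and the later-peaking genes LUX, PRR1 and GI lower. Of 7 measured genes, LHY rose, LUX, PRR1, GI and PRR37 fell, and PRR73 and PRR95 did not pass (1 and 4 when adjusted over the list alone). LHY was at 10.51 ± 0.0095 in osmads32 against 7.66 ± 0.22 in wild type (SD, n = 3; adjusted p = 2.5e-05), while LUX fell to 3.85 ± 0.12 (adjusted p = 1.4e-05). GI, a regulator of flowering time, was at 9.79 ± 0.062 against 11.30 ± 0.079 (adjusted p = 3.3e-05), and PRR1 at 5.94 ± 0.16 against 7.46 ± 0.067 (adjusted p = 9.97e-05). A dimmer LHY probe set was at the background in both genotypes (2.68 and 2.78), and the mean with it rose by 1.37. With members moving in both directions, the list did not pass camera (adjusted p = 0.163, or adjusted p = 0.715 with an estimated correlation). The hour of collection is not given in the labels.

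**Figure D3:**
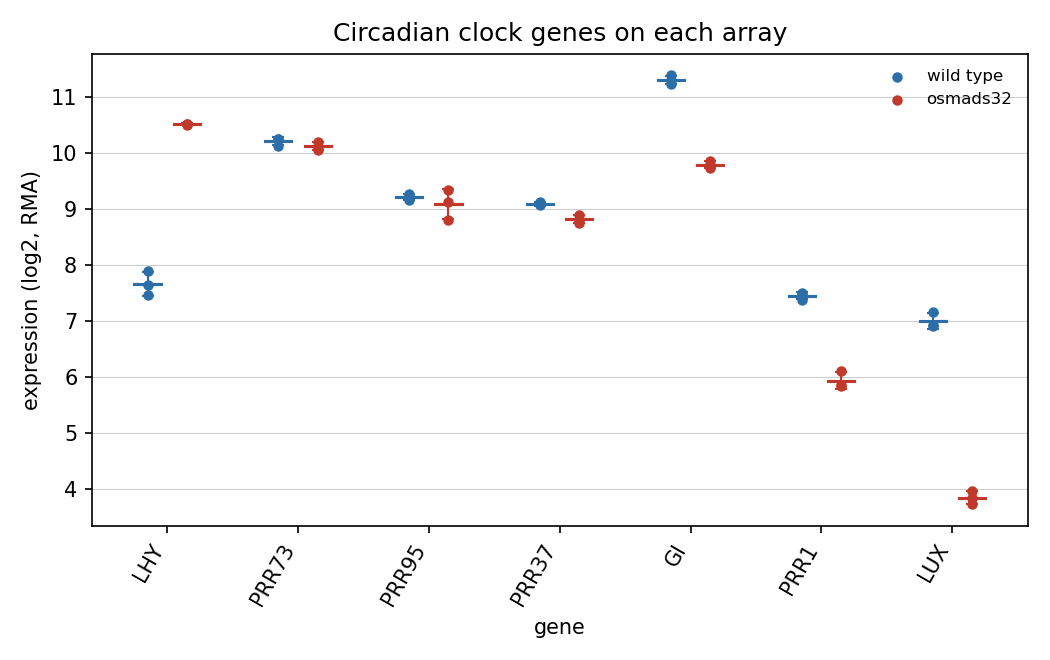
Log2 expression (RMA, vertical axis) of the 7 circadian clock genes (horizontal axis) on each array, with points for the 3 osmads32 arrays in red and the 3 wild-type arrays in blue, horizontal bars at the means and vertical bars for the SD. LHY is higher in all osmads32 arrays, and GI, PRR1 and LUX are lower in all of them.

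The named genes with the largest increases included 2 fermentation enzymes, PDC1 and Adh2. Pyruvate decarboxylase PDC1, an enzyme of ethanol fermentation, rose by 4.97 from 5.35 ± 0.17 to 10.32 ± 0.46 (SD, n = 3; adjusted p = 4.0e-05), and alcohol dehydrogenase Adh2 rose by 3.35 to 6.87 ± 0.31 (adjusted p = 0.000109). The trehalose-6-phosphate phosphatase TPP1 rose by 2.95 (SE 0.49, adjusted p = 0.0054), with a wide spread in both genotypes. The pathogenesis-related protein PBZ1 rose by 2.54 (adjusted p = 5.5e-05). LFL1, a B3-domain factor that delays flowering, rose by 2.25 to 6.07 ± 0.32 (adjusted p = 0.000389). HSFA2A, LHY, HSP24.1, HSP17.4 and HSP18.1 complete the 10.

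The named genes with the largest decreases included protein kinases, a dehydrin and clock genes. The stress- and abscisic-acid-activated protein kinases SAPK9 and SAPK10 fell by 3.15 and 1.86, SAPK9 from 8.59 ± 0.11 to 5.45 ± 0.15 (SD, n = 3; adjusted p = 1.4e-05). The dehydrin RAB16B fell by 2.21 (SE 0.36, adjusted p = 0.00527). The light-regulated gene LIR1 fell by 2.38 (adjusted p = 0.000676), phytoene synthase PSY3 by 1.74, and the beta-expansin EXPB11 by 1.54. LUX, HSFC1B, PRR1 and GI complete the 10.

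Genes with no name in the tables used here held the extremes, and those given here were chosen after their values were seen. LOC4331398 was at 12.02 ± 0.012 in osmads32 and 3.22 ± 0.19 in wild type (SD, n = 3), a difference of 8.80 that makes it the largest increase of all genes. LOC4331781 rose by 5.44 and LOC4342642 by 5.14. LOC4324731 had the largest decrease, from 10.56 ± 0.084 in wild type to 4.73 ± 0.53, followed by LOC4332353 with a difference of -3.40.

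Cell-wall and cell-cycle genes shifted in both directions. In the cell-wall expansion list, 8 of 59 genes rose and 18 fell (9 and 19 when adjusted over the list alone). The expansins EXPA5, EXPA29 and EXPB4, which loosen cell walls, fell by 0.91, 0.91 and 0.73 (adjusted p of 0.000141 or less). In the cell-cycle list, 15 of 78 genes rose and 9 fell (the same numbers when adjusted over the list alone). The cyclins CYCD4-2 and CYCD3-2 rose by 0.53 and 0.37, and so did the cyclin-dependent kinase inhibitor KRP5, by 0.72 to 10.74 ± 0.059. Core histones had 0 of 6 genes past limma's test over all genes or the list alone, with 2 at an unadjusted p under 0.05. Class III peroxidases and laccases had 0 of 13, with 0 at an unadjusted p under 0.05. For cytosolic ribosomal proteins, 2 of 26 rose and 3 fell (1 and 3 when adjusted over the list alone): RPS10-1 and RPS26 were higher, and RPL18, RPL5 and RPS7 were lower, the last with a call that ended in 6 of 13 alternatives. None of these 5 lists passed camera (adjusted p from 0.408 to 0.722).

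Hormone genes moved in both directions, and most members of the auxin and cytokinin lists did not pass. Of 60 auxin genes, 8 rose and 16 fell, with 36 not past (8 and 17 when adjusted over the list alone). The auxin transporter PIN10A fell by 0.59, the Aux/IAA repressors IAA24 and IAA13 by 0.70 and 0.51, and the auxin response factor ARF3 rose by 0.46. Of 31 cytokinin genes, 2 rose and 11 fell, with 18 not past (4 and 11 when adjusted over the list alone). The response regulator RR5 rose by 1.51 to 6.47 ± 0.22 and the cytokinin oxidase CKX11 by 0.97, while the cytokinin-activating enzymes LOGL3 and LOGL6 fell by 0.62 and 0.51. Of 13 gibberellin genes, CIGR2, SLR1, KAO and CIGR1 rose, CPS1 and CYP701A6 fell, and 7 did not pass (4 and 5 when adjusted over the list alone). The KAO call ended without osmads32 replicate 3 or wild-type replicate 2 (highest adjusted p = 0.0712). CIGR2 rose by 0.71, and CPS1, which catalyses an early step of gibberellin synthesis, fell by 0.60. Of 48 jasmonate, wounding and pathogenesis-related genes, 7 rose and CHT10 fell (4 and 1 when adjusted over the list alone), with AOS1, an enzyme of jasmonate synthesis, up by 0.39 and the repressor JAZ12 by 0.56. Camera passed none of these 4 lists (adjusted p of 0.65, 0.41, 0.65 and 0.0773 in this order), and the last passed in 4 alternatives (lowest adjusted p = 0.0111). It did not pass with fry (adjusted p = 0.0825) or with the correlation estimated (adjusted p = 0.715 with an estimated correlation).

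Homeodomain-leucine zipper genes fell in 9 of 34 cases, and ROC2 and HOX12 rose (2 and 9 when adjusted over the list alone). HOX14 fell by 1.05 to 7.92 ± 0.11 (SD, n = 3; adjusted p = 0.000377) and HOX16 by 0.64 in its brightest probe set (-0.40 over the mean of its sets). Meiosis genes fell in 3 of 7 cases (3 also when adjusted over the list alone), led by the crossover helicase MER3 with a difference of -0.39, while HEI10 and PAIR2 fell by 0.26 and 0.19 with calls that ended in 6 of 13 alternatives each. Of 11 tapetum and anther genes, TDL1A rose by 0.59 and MSP1 by 0.23 (2 and 0 when adjusted over the list alone), and the MSP1 call ended in 6 alternatives. In the photosynthesis list, LHCP, PSAG, CAB2R and PSB28 rose, LFNR1 and OEE3 fell, and 7 of 13 did not pass (4 and 2 when adjusted over the list alone), with differences of 0.69 for LHCP and -1.06 for LFNR1. Diterpenoid phytoalexin genes had 2 of 11 higher (2 when adjusted over the list alone), CYP71Z7 and MAS, at low levels of 3.04 and 3.55 in osmads32 and with calls that ended in 2 and 5 of 12 alternatives. In the wax and lipid-transfer list, LTPL1 rose by 0.26 and LTP2-B fell by 0.57, and 5 of 7 did not pass (2 and 1 when adjusted over the list alone), with calls that ended in 6 and 3 of 13 alternatives. These lists did not pass camera (smallest adjusted p = 0.37). PRR37, HSP17.9B, RPS26, CIGR1, CYP701A6, HOX12, CAB2R and PSB28 lie outside the rule for named genes and were named after their values were seen.

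Control probe sets for reporter genes differed with genotype as well. Of 64 such sets, 4 were higher in osmads32, with a lowest osmads32 array of 7.23 and a highest wild-type array of 3.64. By their identifiers, most of these 4 belong to a single sequence. Leaving all 64 out gave 5134 changed probe sets and 580 changed at least 2-fold.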

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

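Both tests in this part were chosen only after the result was seen. Control probe sets for reporter genes, which match no rice gene, were not meant to be compared, yet 4 of 64 were higher in osmads32 by 3.74, 6.85, 7.32 and 6.67 on the log2 scale. By their identifiers, the sets at 6.85, 7.32 and 6.67 belong to a single sequence and the set at 3.74 to another, so the 4 are not separate signals. Among these 4, the lowest osmads32 array was at 7.23 and the highest wild-type array at 3.64. A candidate explanation is a transcribed reporter or vector sequence in the osmads32 line. The count of sets above the upper quartile on all osmads32 arrays and below the median on all wild-type arrays was 4, but these are the sets that raised the explanation, so the count decides nothing and the explanation stays open. A difference in background or hybridisation left in these values would have moved the other 60 sets too. Their median difference was 0.0116 (SD 0.116), and limma called 0 of them (3 at an unadjusted p under 0.05), so they did not share the rise. RMA removes differences across whole arrays before this test, so the test cannot exclude that the arrays differed in background or hybridisation. The labels describe osmads32 as a mutant and give no construct, so whether other differences follow from an inserted sequence, and not from the loss of OsMADS32, was not tested.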

How the results depend on the processing

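No tests were chosen only after the results were seen, except leaving out the 64 reporter control sets; every other alternative was chosen before the data were examined. With the reporter sets out, 5134 probe sets changed, 580 of them at least 2-fold.

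The count of 5133 changed probe sets moved with the threshold, the probe sets and arrays included, and the fit. Leaving out dim probe sets gave 7094 (2513 higher, 4581 lower), so the share called depends on how many dim sets are tested. An intensity trend with robust variance gave 7843 (4958 lower), an adjusted p below 0.01 gave 2156 (893 higher, 1263 lower), and treat with a fold of 1.2 gave 1145 (582 higher, 563 lower), which raised the share higher from 38.4% to 50.8%. Array weights gave 7645 probe sets (2998 higher, 4647 lower), and 8340 genes (2972 higher, 5368 lower) against 5240. At the level of genes the weights stopped before convergence, with 6.07 for osmads32 replicate 3, so this count is not reliable. Leaving out 1 array gave 2579 to 4301 probe sets (1061 to 1633 higher, 1518 to 2694 lower) and 3141 to 5163 genes (1156 to 1670 higher, 1985 to 3493 lower). The lowest came without osmads32 replicate 3; the cause was not tested. The 2-fold count of 584 ranged from 549 to 611.

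Fitting the replicate block gave 4126 probe sets (3853 called both ways), 594 at least 2-fold, 4304 genes and 2 lists. It ended the calls of 8 of the 129 genes compared, OsMADS15 among them (adjusted p = 0.0703), and changed no other call on them. Deviations of arrays with the same number correlated at 0.0574, 0.0104 and 0.0399, below the limit of 0.1 set for treating numbers as pairs, although 5 of 6 arrays correlated best with their own number, a hint from the data that the labels do not explain.

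The list result changed with the test used. Against 1 list with camera at its preset, 0 passed with an estimated correlation (0 at an unadjusted p under 0.05), 10 with fry (heat shock, clock, SBP, cell-wall expansion, YABBY, homeodomain-leucine zipper, auxin, meiosis, other MADS-box, and inflorescence and spikelet meristem), 2 without dim probe sets, and 1 to 2 with an array left out. The heat-shock list had an adjusted p = 0.715 with an estimated correlation.

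Of 1664 comparisons on single genes, the extreme genes without a name included, 1540 kept their call, 86 lost it, 38 gained one and 0 reversed. Of 355 on lists, 341 kept it, 1 lost it and 13 gained one. No alternatives were run for the level of OsMADS32, which has no value here. Apart from the extreme genes without a name, none were run for genes given outside the fixed rule, among them the MCM genes, PDC2, PRR37 and HSP17.9B.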

Other observations

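The tests on collection time, a single stressed sample, RNA quality and developmental stage were chosen only after the results were seen, as were the gene groups in this part. The tests on other splits of the arrays were chosen before.

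Most measured genes of the MCM family, whose members MCM2 to MCM7 form the core of the replicative helicase, rose in osmads32. Of 8 MCM genes, 7 rose, from 0.28 for MCM3 to 0.47 for MCM7 and 0.53 for MCM8 (adjusted p = 0.00341 for MCM7), and MCM9 did not pass. MCM8 was at a low level, 3.80 against 3.27 in wild type. Among 55 name families taken from 2452 named genes, MCM and HSP were the 2 enriched for higher genes (Fisher's exact tests, adjusted p = 0.000476 and 0.00161 over 110 tests). These tests treat genes as independent, and the family was noticed after its values were seen.

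Some genes known from low-oxygen metabolism rose, picked after their values were seen and with no test of them as a group. Beside PDC1 and Adh2, the pyruvate decarboxylase PDC2 rose by 0.98 (adjusted p = 0.000435), and the non-symbiotic hemoglobins NSHB2 and NSHB1 rose by 1.86 and 0.71, while PDC3 did not pass. NSHB1 was at a low level, 3.97 against 3.27 in wild type. Oxygen supply was not recorded in the labels, and the cause was not tested.

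Some genes of abscisic acid signalling fell, also picked after their values were seen and not tested as a group. The 5 measured SAPK kinases fell: SAPK9, SAPK10, SAPK1, SAPK2 and SAPK8, with SAPK1 at -0.63. Of 4 RAB16 and RAB21 dehydrins, RAB16B, RAB21 and RAB16C fell and RAB16D did not pass, and Dhn1 and rab25 fell by 0.88 and 0.73. ABA8OX1, which breaks down abscisic acid, rose by 1.94 (adjusted p = 0.00109), whereas ABA8OX2 fell by 0.88.

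The heat-shock and clock shifts could share a cause outside the genotype, such as genotypes collected at different hours. LHY minus the mean of GI, PRR1 and LUX differed by 4.91 (SE 0.16), but these are the genes that raised the explanation, so the value decides nothing. Collection hour and an effect of osmads32 on the clock both stay open, since the labels give no hour. The heat-shock rise was not confined to a single osmads32 array. The lowest osmads32 array exceeded the wild-type mean of the heat-shock genes by 0.518, against a wild-type SD of 0.0488. Stress in a collection shared by all osmads32 arrays stays open, since the labels do not say whether replicates came from separate plants or plots. For RNA quality, the 3′ to 5′ gap of control transcripts differed by 0.0395 (SE 0.14), so no large difference in transcript truncation was seen. Other differences in RNA quality or handling would not show in this gap and stay open.

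The rise of OsMADS6, OsMADS17 and DL with the fall of SPL14, FZP and OsMADS14 might reflect osmads32 inflorescences being further along at the same length. A large enough advance would raise later-acting meiosis and tapetum genes, but over 18 genes their mean differed by -0.0287 (SE 0.040). Meiosis genes were at -0.15 and tapetum genes at 0.05. A small advance from the onset of inner floral organ development need not reach genes that act later, so this test leaves the question open.

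Splitting the 6 arrays in all 10 ways showed how far counts depend on the genotypes. The real split alone (1 of 10) gave its 5133 probe sets, and likewise 1 of 10 gave the 584 at least 2-fold and 1 of 10 the 5240 genes. In the other 9, limma gave 0 for each, with 1139 to 2695 probe sets and 198 to 697 genes at an unadjusted p under 0.05. Each of these splits mixes the genotypes in both groups, which puts the genotype difference into the spread within groups. Counts near 0 for probe sets and genes were thus largely built in, and they do not measure what chance would give. For lists, 10 of 10 splits gave at least the 1 list found, with up to 4, and heat shock passed in 6 of the other 9 (smallest adjusted p = 0.00367, against 1.1e-07). Each other split keeps part of the genotype difference, so passes there are no rate of chance passes. With 10 splits the smallest attainable share is 0.1.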
